A study of Gallus gallus with 6 samples.

How the data were processed

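RNA was measured in 6 libraries of the chicken B cell line DT40, 3 from wild type cells and 3 from Bach2 knockout cells. Per the labels' protocols, the cells were grown in RPMI medium with fetal calf and chicken serum, and total RNA was extracted from independent cultures of each genotype and made into Illumina libraries. The labels do not say whether the knockout cultures came from more than 1 knockout clone, so that p-values measure the spread between cultures, not between clones. The deposited columns of the knockout libraries are named Bach2ko1 with a replicate number, which may point to 1 clone. With 1 clone, no difference between the genotypes could be told apart from a difference particular to that clone. The series text states paired-end sequencing on a HiSeq2500. Groups were taken from the genotype label and replicate numbers from the sample titles.

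The authors deposited 2 tables with 17108 Ensembl genes in 6 columns each. One holds raw counts: the deposited values are whole numbers that sum to between 8999010 and 20647281 per library, although its name speaks of RPKM. The other holds values that were read as RPKM, because each deposited value equals the gene's count times 1 constant per gene and 1 per library; against wild type replicate 1 these library constants ran up to 2.29 in wild type replicate 3, close to the inverse ratio of total counts (2.29). Per the submitters' processing notes, bcl2fastq 1.8.4, TopHat2 2.1.0, Subread 1.5.0, edgeR, limma and the build galGal4 were used. Which step each served is not given in the sources used here. Nor are the annotation, the gene lengths and whether strand was used in counting. Without strand information, reads of overlapping and antisense genes cannot be told apart, and near-identical copies may share reads. 4849 genes had no count in any library. Symbols were taken from the tables, where 14007 genes have one, 397 have more than 1, and 1 had been turned into a date; a list member was matched to any symbol of a row. All columns of values were matched to a sample by name.

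Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its default settings (9159 genes), libraries were scaled by TMM (factors 0.985 to 1.02), and genotype was tested with glmQLFit and glmQLFTest on all 6 libraries without covariates, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05; a second count required an absolute log2 fold change of at least 1. The common biological coefficient of variation was 9.23%. CPM values are counts scaled by TMM-adjusted library totals, and the SE of a log2 fold change was derived as its size divided by the square root of the F statistic. Where a gene had no count in any knockout library, the fold is a lower bound from a floor of 3 counts over the 3 libraries, or 0.0593 CPM; in single libraries 3 counts correspond to between 0.147 and 0.339 CPM. Floors cover counting error only. No pair of libraries of a genotype was a duplicate: chi-square per degree of freedom between their counts was 3.20 to 8.47 in wild type and 6.67 to 29.4 in the knockout.

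Gene lists (25, with 1026 entries) were written before the data were examined, as were the design and the alternatives. Lists with at least 5 tested genes (23) and chromosomes with at least 20 (28) were tested against all other genes with camera of limma 3.58.1, with a preset correlation of 0.01, on log2 CPM with a prior count of 2, and adjusted over lists or over chromosomes. Of 14007 NCBI gene identifiers in the tables, 13400 were found in a gene table of the assembly GRCg7b. It was used to group genes by chromosome and to order them by start position, although its build differs from that of the counts. For genes on chromosome 3, the fit was repeated with the median log2 fold change of that chromosome as an offset in the knockout libraries, an alternative chosen after the data were seen, as was leaving out that chromosome.

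The genes named are BACH2; UNG, PRDM1, XBP1, IRF4, BCL6, PAX5, EBF1 and HMOX1; the 8 largest increases and 8 largest decreases among genes past the threshold with a proper symbol, a mean of at least 1 RPKM and no overlap between the genotypes; and, for each list, up to 3 members past the threshold with the largest absolute log2 fold change. Another 43 genes help complete a list's count of 5 or fewer risen or fallen genes and were chosen after their values were seen. A gene and a list named in the design, with the members named for that list, and some members of other lists are not reported here.

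The tests were checked on simulated data: negative binomial counts for the 9159 genes of the comparison of knockout against wild type, with 200 genes changed. The fit called 74.6% of 67 genes changed 1.5-fold, 89.6% of 67 changed 2-fold and 98.5% of 66 changed 4-fold, and 13 of 8919 unchanged genes. Camera called a shifted list and 0 of 20 unshifted lists. The simulated genes were drawn independently of each other, so that this does not check camera on lists with correlated members. The estimated correlation in the measured lists reached 0.811, for cholesterol biosynthesis. The alternatives were DESeq2 size factors, library totals without TMM, all genes with any count, genes with a mean of at least 1 RPKM, limma on log2(RPKM + 0.5), log2(RPKM + 0.1) and log2(RPKM + 1), DESeq2 1.42.0, leaving out each library, and the replicate number as a block; for lists and chromosomes also camera with estimated correlation, and for lists fry and quantile normalization.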

Results

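Gene expression was measured by RNA sequencing in DT40, a chicken B cell line that goes on diversifying its immunoglobulin genes in culture. Bach2 is a transcriptional repressor of B cells. The title of the series places it in the regulation of immunoglobulin gene conversion and somatic hypermutation. Wild type cells (named Clone 18) were compared with Bach2 knockout cells, with 3 libraries of each genotype from independent cultures. The deposited gene counts summed to 20647281, 13878690 and 8999010 in wild type replicates 1, 2 and 3. They summed to 12934863, 17779060 and 19316678 in knockout replicates 1, 2 and 3. The 10 most abundant genes took between 9.33% and 11.2% of the counts of a library. Across the 9159 genes tested, Pearson correlations of log2 CPM were 0.992 to 0.994 between wild type libraries, 0.986 to 0.994 between knockout libraries and 0.960 to 0.969 between genotypes. These are correlations across genes, which are not independent replicates. The first principal component held 72.6% of the variance and separated the genotypes. The second held 13.0% and set knockout replicate 1 apart from knockout replicates 2 and 3. Fold changes below are log2 of knockout over wild type, with the standard error (SE) of the fit. Adjusted p-values are those of edgeR's two-sided quasi-likelihood test over all tested genes unless another test is named.

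The first question was whether the knocked-out gene and a set of B cell genes named in advance differed between the genotypes. BACH2 (ENSGALG00000015605) fell from 6.35 ± 0.251 CPM in wild type to 2.85 ± 0.457 CPM in the knockout (SD, n = 3 each). Its log2 fold change was -1.16 ± 0.20 (SE, edgeR adjusted p = 0.00144). Reads on the gene remained in every knockout library, with 34, 61 and 50 counts in replicates 1, 2 and 3, against 135, 87 and 54 in the wild type. The counts cover the whole gene model and do not show which part of it the remaining reads came from. UNG, a uracil glycosylase of base excision repair, had 222 ± 14.0 CPM in wild type and 213 ± 22.5 CPM in the knockout (SD, n = 3 each). That difference lay within the spread between replicates (-0.059 ± 0.088, edgeR adjusted p = 0.645) and was 0.025 without knockout replicate 1.

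Among the transcription factors of that set, BCL6, a repressor of germinal centre B cells, fell by 0.98 ± 0.14 on the log2 scale (SE, edgeR adjusted p = 0.000536). PAX5 and EBF1, which specify B cell identity, fell by 0.42 ± 0.067 and 0.45 ± 0.081. XBP1, a driver of the secretory programme of plasma cells, rose from 190 ± 9.59 to 253 ± 21.5 CPM (SD, n = 3 each). HMOX1, the haem oxygenase gene that BACH proteins are known to repress, rose from 93.4 ± 8.25 to 138 ± 2.48 CPM. The log2 fold changes of XBP1 and HMOX1 were 0.41 ± 0.079 and 0.56 ± 0.077. IRF4, a regulator of plasma cell differentiation, did not pass (-0.15 ± 0.087, edgeR adjusted p = 0.214). Without knockout replicate 1, IRF4 was at -0.21 with an adjusted p of 0.0394, and over all alternatives its adjusted p ran from 0.0394 to 0.633. PRDM1, the gene of the plasma cell regulator BLIMP1 and a known Bach2 target, was below the count filter. It had 10, 8 and 4 counts in the wild type libraries and 0, 9 and 9 in the knockout libraries. Fitted without the filter, its log2 fold change was -0.56 ± 0.74 (edgeR adjusted p = 0.616). These few counts showed no difference and do not exclude one.

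**Figure D1:**
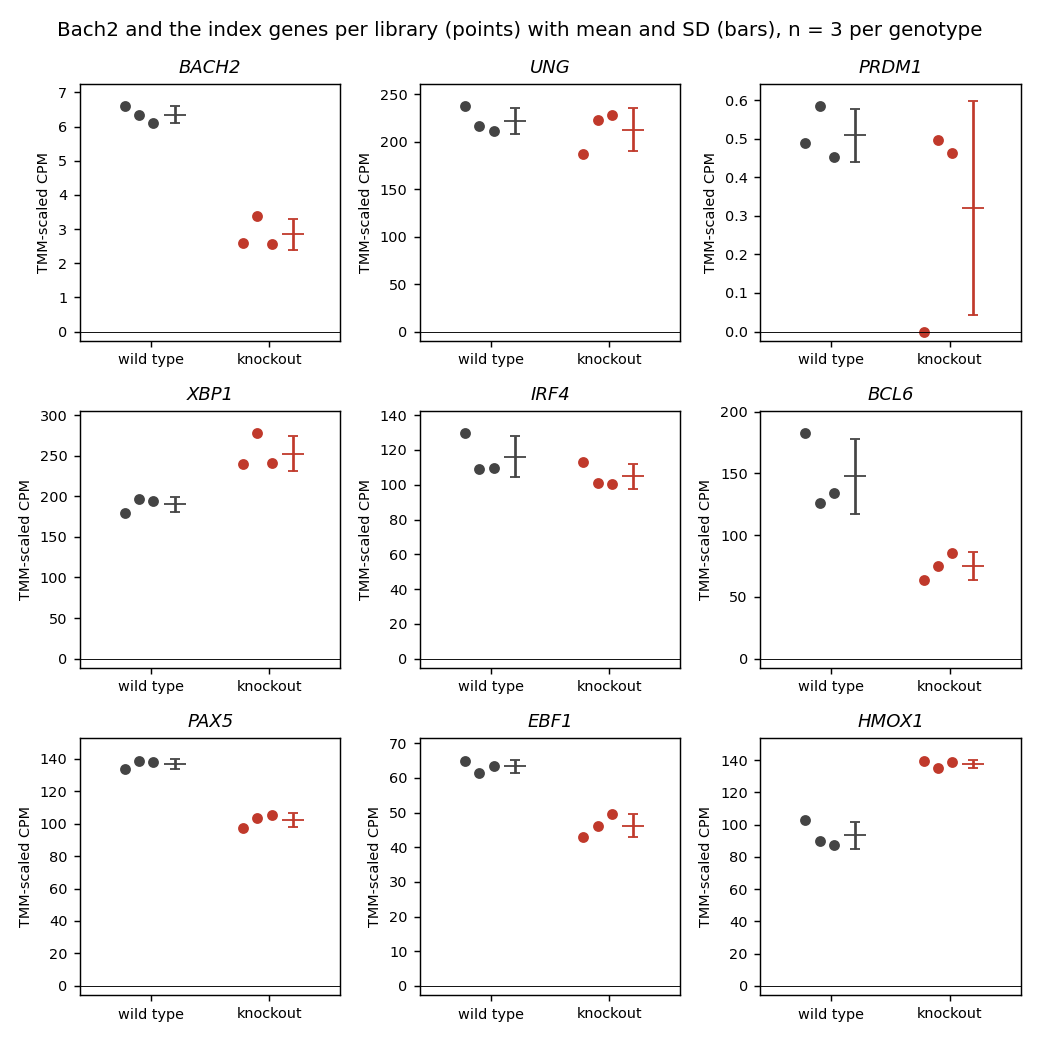
Expression of BACH2 and of 8 index genes in TMM-scaled CPM (vertical axes, linear) in the 3 wild type and 3 Bach2 knockout libraries; points are libraries and bars the mean and SD. BACH2, BCL6, PAX5 and EBF1 lie lower and XBP1 and HMOX1 higher in the knockout, while UNG, IRF4 and PRDM1 did not pass or were not tested.

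The second question was how many genes differed between the genotypes. Of 9159 genes tested, 1163 were higher and 1647 lower in the knockout at an adjusted p under 0.05, and 6349 did not pass. With library totals in place of TMM, 1427 were higher and 1491 lower, and with the genes of chromosome 3 taken relative to its median, 1183 were higher and 1231 lower. At least 2-fold changes were seen for 112 genes that were higher and 486 that were lower. The values of the genotypes did not overlap for 4232 of the tested genes, or 46.2%, where chance gives 10% with 3 libraries against 3. The number of higher genes also depended on single libraries. It was 639, 643 and 645 without wild type replicate 1, 2 or 3 and 747 without knockout replicate 2. Without knockout replicate 1, 1483 genes were higher and 1953 lower. When only genes with a mean of at least 1 RPKM were tested, 65 genes were at least 2-fold higher and 287 at least 2-fold lower.

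The largest decreases included genes with no count left in any knockout library. EFHD2, a calcium-binding protein gene, had 11.7 ± 1.24 CPM in wild type (SD, n = 3) and 0 in the knockout. That is at least 198-fold lower against a floor of 3 counts over the 3 knockout libraries. On the same floor, CD276, a surface protein of the B7 family, was at least 191-fold lower and THBS4 (thrombospondin 4) at least 120-fold lower. OAF was at least 80.1-fold lower and MANSC1 at least 67.2-fold lower. DDX25, an RNA helicase gene, fell from 12.9 ± 1.09 to 0.166 ± 0.0902 CPM (SD, n = 3 each; log2 fold change -6.11 ± 0.29). FKBP9 fell from 18.2 ± 0.862 to 0.405 ± 0.221 CPM and PLEKHO1 from 22.9 ± 1.84 to 0.639 ± 0.0652 CPM. The largest increases were smaller and started from low levels. PPAPDC1A rose from 0.684 ± 0.119 to 7.99 ± 1.12 CPM (SD, n = 3 each; log2 fold change 3.51 ± 0.25). SLC7A11, the light chain of the cystine/glutamate exchanger, rose from 5.25 ± 1.38 to 47.2 ± 13.2 CPM (log2 fold change 3.23 ± 0.25). The microRNA gene MIR222 rose by 2.81 ± 0.57, CYGB (cytoglobin) by 2.73 ± 0.46 and DPCD by 2.38 ± 0.31 on the log2 scale. TTC29 rose by 2.34 ± 0.25 and SLC9A9 by 2.20 ± 0.24. DDO (D-aspartate oxidase), which lies on chromosome 3, rose by 2.79 ± 0.42. The largest edgeR adjusted p among these increases and decreases was 0.00391, for MIR222.

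The third question, set because a knockout is a clone of a cell line, was whether whole chromosomes differed. Genes were grouped and ordered with a gene table of the GRCg7b assembly, which differs from the build named for the counts. Chromosome 3 was lower as a whole in the knockout. Of its 688 tested genes, 644 had a negative log2 fold change, 484 were called lower and 8 higher, and the median was -0.45. The 7622 genes placed on other chromosomes had a median of 0.028, with 1031 called lower and 1077 higher. Chromosome 3 held 7.51% of the tested genes and 29.4% of the genes called lower. Camera, which compares a set with all other genes, gave it an adjusted p of 4.76e-36, and adjusted p = 0.0225 with an estimated correlation. Its median against the wild type mean was -0.42, -0.45 and -0.48 in knockout replicates 1, 2 and 3. In 28 bins of about 25 neighbouring genes along the chromosome, medians ran from -0.62 to -0.30. Among other chromosomes, camera called 25 lower (median -0.20, adjusted p = 0.00606) and Z, 2 and 1 higher (medians 0.11, 0.083 and 0.083). With an estimated correlation these calls were lost (adjusted p = 0.800 for 25, 0.380 for Z, 0.451 for 2 and 0.345 for 1). Without knockout replicate 1, camera called chromosome 3 lower and 0 chromosomes higher, with 4 higher at an unadjusted p under 0.05. BACH2 had no entry in that gene table and is 1 of 849 tested genes that were not placed. Whether it lies on chromosome 3 was thus not determined here, and its fold change was not taken relative to that chromosome.

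**Figure D2:**
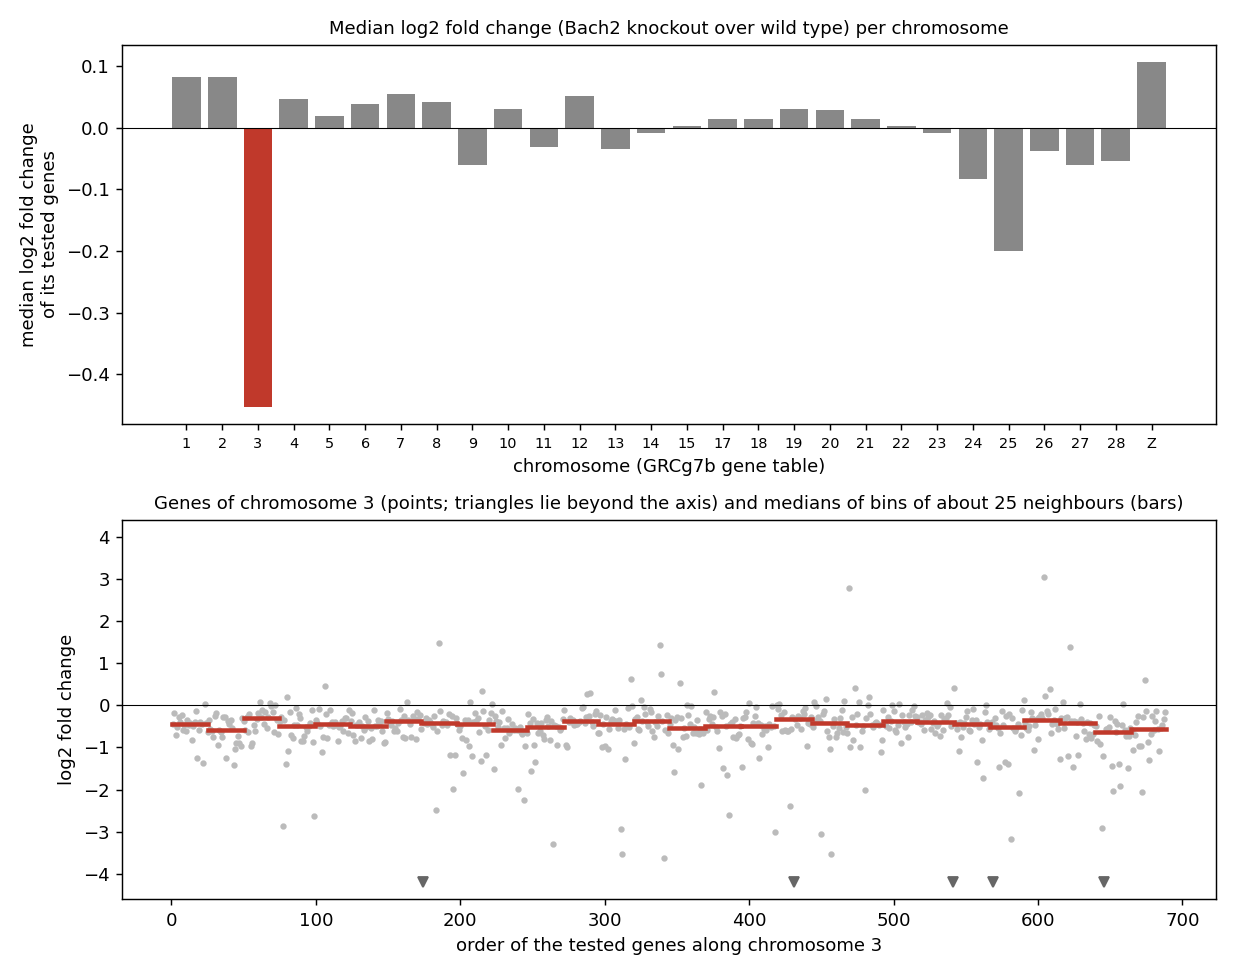
Top, median log2 fold change (knockout over wild type) of the tested genes of each chromosome with at least 20 of them; bottom, log2 fold change of each of the 688 tested genes of chromosome 3 in their order along it (points), with medians of bins of about 25 neighbours (bars) and triangles for genes beyond the axis. Chromosome 3 has a median of -0.45 and its 28 bins lie between -0.62 and -0.30.

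The fourth question was which groups of genes moved together, for 25 lists of genes. Camera called 2 lists higher and 4 lower among the 23 lists with at least 5 tested genes. With an estimated correlation, camera called 0 lists. At an unadjusted p under 0.05, limma's camera then left the lists of endoplasmic reticulum stress (0.00286) and B cell receptor signalling (0.0437). Fry, which does not compare a list with other genes, called 9 lists lower and 2 higher at an adjusted p under 0.05. The 9 were the 4 that camera called lower (B cell transcription factors, B cell receptor signalling, chemokine receptors and adhesion, and T cell markers) and homologous recombination, apoptosis, interferon response, MHC class II and macrophage and granulocyte markers. The 2 were endoplasmic reticulum stress and the plasma cell programme. The median of each list that lay within 0.1 of 0 moved by over 1.5 times without at least 1 of the libraries. Such medians changed sign for base excision and mismatch repair without knockout replicate 2 (-0.014), G2 and mitosis genes without knockout replicate 1 (-0.014) and p53 targets without wild type replicate 1 (-0.023). That of oxidative phosphorylation changed sign without wild type replicate 1 (-0.0077) and without knockout replicate 2 (-0.016). Among the genes named below, the calls of NBN, TNFRSF13B, EGR1, ATF3, CENPF, GADD45B, BTG2, BCL2, XAF1, ATP5L, NDUFAB1 and FBN1 were each lost without at least 1 of the libraries. Their edgeR adjusted p in those fits ran from 0.0522 (CENPF, without knockout replicate 2) to 0.214 (EGR1, without wild type replicate 1). Another 43 genes, named after their values were seen, help complete counts of 5 or fewer, and 30 of these lost the call without at least 1 of the libraries. The other 13 were BRCA2, LIG3, MYC, PDIA6, DTL, RRM2, HMGB2, ENO1, RPS7, NDUFB1, ITGB1, CD3D and CD247.

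Genes of endoplasmic reticulum stress and secretion were higher in the knockout. Of 40 tested, 26 rose, 2 fell and 12 did not pass, and the counts adjusted over the list alone were also 26 and 2. The median was 0.30 (camera adjusted p = 7.55e-07; adjusted p = 0.0659 with an estimated correlation). CHAC1, a glutathione-degrading enzyme of the stress response, rose by 1.26 ± 0.28 (log2, SE) and HERPUD1, which acts in degradation of misfolded proteins, by 0.81 ± 0.11. ERN1, the gene of the stress sensor IRE1, fell by 0.81 ± 0.16, and PDIA6, on chromosome 3, by 0.31 ± 0.065. Of 14 plasma cell programme genes, 6 rose, 4 fell and 4 did not pass (6 and 4 adjusted over the list alone; median 0.19, camera adjusted p = 0.164). Fry gave that list an adjusted p of 0.00148, and camera 0.104 to 0.499 over the alternatives. Its median was 0.094 without wild type replicate 2, 0.30 without wild type replicate 3 and 0.33 with quantile normalization. IGJ, the joining chain of secreted IgM and IgA, rose 2.27-fold, from 530 ± 67.9 to 1200.4 ± 105 CPM (SD, n = 3 each; edgeR adjusted p = 1.50e-05). TXNDC11, a thioredoxin-domain protein of the endoplasmic reticulum, rose by 0.55 ± 0.068. TNFRSF13B, the receptor TACI, fell by 0.59 ± 0.14. The other lower genes were EAF2 (-0.38), MZB1 (-0.31) and SDC1 (-0.30), of which SDC1 lies on chromosome 3. SDC1 (edgeR adjusted p = 0.0495) kept its call in 1 alternative, lost it in 14 and stood at 0.15 relative to that chromosome's median. MZB1 kept its call in 8 alternatives and lost it in 8, and EAF2 kept its call in 9 and lost it in 7. MZB1 reached -0.20 with 1 library left out.

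B cell transcription factors were lower: 15 of 26 fell, 3 rose and 8 did not pass (17 and 3 adjusted over the list alone). The median was -0.37 (camera adjusted p = 0.000322, and 0.305 with an estimated correlation). Of the 26 genes, 4 lie on chromosome 3, and 3 of these fell. Without the genes of that chromosome the median was -0.28 (camera adjusted p = 0.000488, and 0.350 with an estimated correlation). The largest decreases in the list were of KLF2 (-3.35 ± 0.63), ID2 (-2.08 ± 0.14) and NFATC1 (-0.98 ± 0.18). KLF2 was low, with 1.61 ± 0.969 CPM in wild type and 0.132 ± 0.0486 CPM in the knockout (SD, n = 3 each). Its log2 fold change ran from -3.71 to -0.68 over the alternatives. ID2 lies on chromosome 3 and stood at -1.63 relative to the median of that chromosome. The higher genes were BACH1 (0.86), ID3 (0.72) and MYC (0.39). Of 31 genes of B cell receptor signalling, 15 fell, 3 rose and 13 did not pass (18 and 4 adjusted over the list alone). The median was -0.22 (camera adjusted p = 0.0014; adjusted p = 0.305 with an estimated correlation). The tetraspanin gene CD82 fell by 3.79 ± 0.53, ITPR3, a calcium channel of the endoplasmic reticulum, by 0.92 ± 0.11 and the adaptor gene BANK1 by 0.77 ± 0.12. CD82 was low, with 2.35 ± 0.581 CPM in wild type and 0.180 ± 0.177 CPM in the knockout (SD, n = 3 each). Its log2 fold change ran from -4.72 to -0.76 over the alternatives. CD72 (0.39), VAV3 (0.35) and PTPN6 (0.29) rose. None of these 6 lies on chromosome 3.

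Of 16 genes of chemokine receptors and adhesion, 8 fell, 1 rose and 7 did not pass, with the same counts adjusted over the list alone. The median was -0.41 (camera adjusted p = 0.0386; adjusted p = 0.305 with an estimated correlation). ITGA9, an integrin subunit, fell from 29.8 ± 4.27 to 2.76 ± 0.715 CPM (SD, n = 3 each). The chemokine receptor gene CCR7 fell by 1.43 ± 0.33 and P2RY8 by 1.32 ± 0.20 (log2, SE). CCR7 ran from -1.67 to -0.37 over the alternatives. The higher gene was ITGB1 (0.38). The camera adjusted p was 0.0506 without wild type replicate 1, 0.0512 without knockout replicate 2, 0.0534 without knockout replicate 3 and 0.0706 with quantile normalization, where the median was -0.21. Over all alternatives with camera it ran from 0.00936 to 0.305, and fry gave 0.00148.

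Genes of MHC class II antigen presentation did not pass as a list (median -0.27, camera adjusted p = 0.0558). Of 13 genes, 4 fell, 1 rose and 8 did not pass (8 and 2 adjusted over the list alone). CD74, the invariant chain, fell from 548 ± 17.1 to 232 ± 23.7 CPM (SD, n = 3 each). The cathepsin genes CTSS and CTSB fell by 0.90 ± 0.090 and 0.87 ± 0.13 (log2, SE). CTSB lies on chromosome 3 and stood at -0.42 relative to its median. IFI30 fell by 0.73 ± 0.19 and RFXAP rose by 0.30 ± 0.096. The camera adjusted p of the list was 0.0291 without knockout replicate 1, 0.0396 without knockout replicate 3 and 0.0141 among genes with a mean of at least 1 RPKM. Over all alternatives with camera it ran from 0.0141 to 0.499, and fry gave 0.00842. The median was -0.18 without knockout replicate 1. Against the wild type mean it was -0.51 in that library and -0.22 and -0.23 in knockout replicates 2 and 3.

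**Figure D3:**
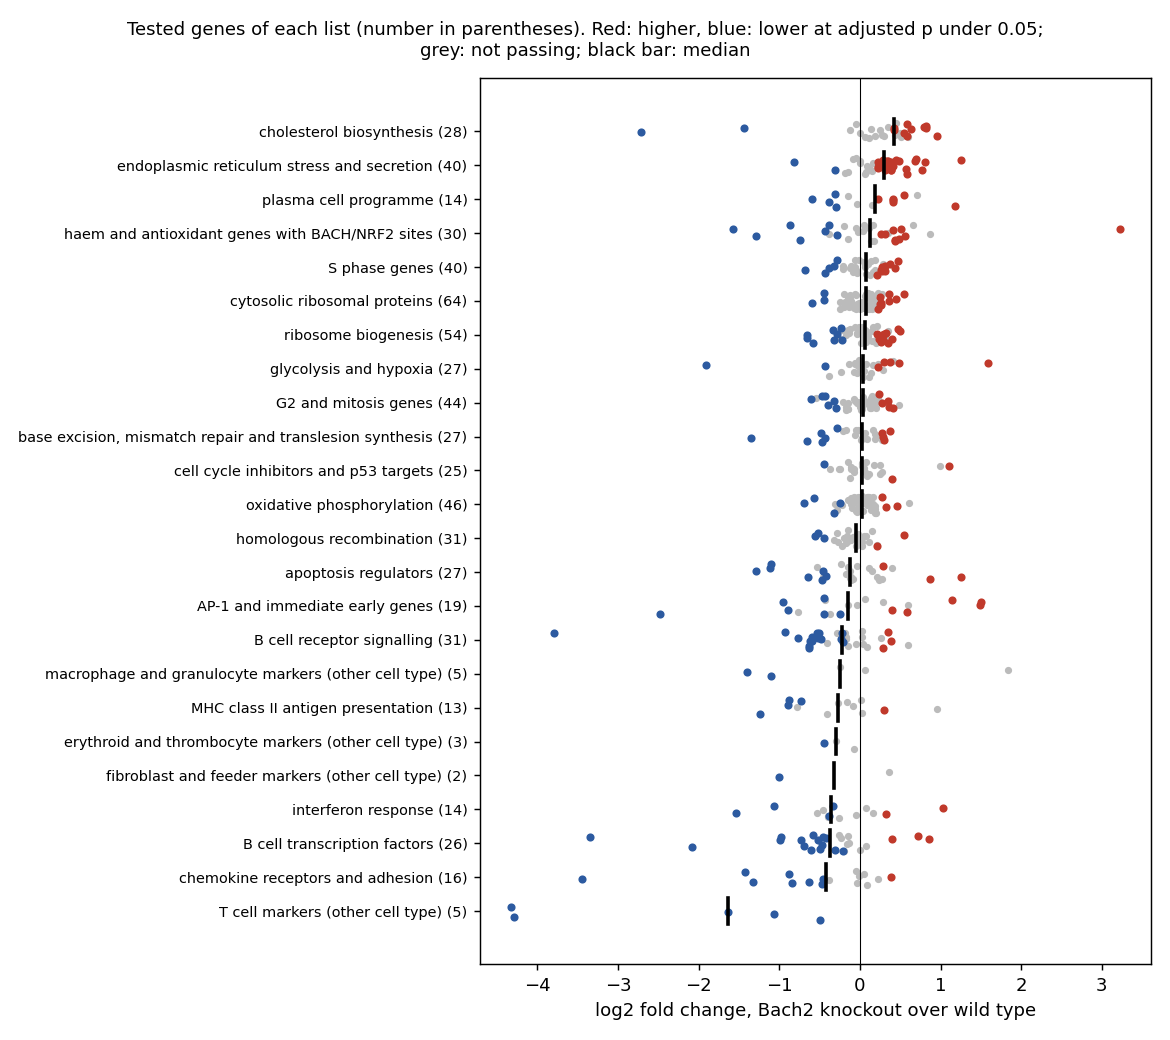
Log2 fold change (knockout over wild type, horizontal axis) of the tested genes of each list, sorted by the list's median (black bar); red and blue points passed at an adjusted p under 0.05, grey points did not. The median of the endoplasmic reticulum list lies at 0.30 and those of the B cell transcription factor and B cell receptor signalling lists at -0.37 and -0.22.

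Of 31 homologous recombination genes, 2 rose, 3 fell and 26 did not pass (1 and 2 adjusted over the list alone; median -0.047, camera adjusted p = 0.556). Camera's adjusted p ran from 0.402 to 0.777 over the alternatives, and fry gave 0.0461. SHFM1 rose by 0.55 ± 0.080 and RECQL by 0.22 ± 0.074. BRCA2, a mediator of recombination, fell by 0.45 ± 0.082 (edgeR adjusted p = 0.00212) and NBN by 0.52 ± 0.16, both on other chromosomes than 3. GEN1, on chromosome 3, fell by 0.56 ± 0.095 and stood at -0.10 relative to that chromosome (adjusted p = 0.458).

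In base excision, mismatch repair and translesion synthesis, 4 of 27 genes rose, 6 fell and 17 did not pass (4 and 7 adjusted over the list alone). The median was 0.030 and the mean -0.077, and camera pointed down (adjusted p = 0.844). The higher genes were REV1 (0.38), LIG3 (0.29), PMS2 (0.29) and PCNA (0.28). Of the 6 lower genes, 5 lie on chromosome 3. POLH, the gene of translesion polymerase eta, fell from 315 ± 8.38 to 123 ± 19.6 CPM (SD, n = 3 each; edgeR adjusted p = 6.93e-06). It lies on chromosome 3, at -0.90 relative to the median of that chromosome (adjusted p = 0.000138). REV3L and PARP1, on the same chromosome, fell by 0.66 ± 0.14 and 0.48 ± 0.065. Relative to its median they were at -0.21 and -0.030 and did not pass (adjusted p = 0.312 and 0.765).

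The haem and antioxidant genes with sites for BACH or NRF2 proteins split: 9 of 30 rose, 7 fell and 14 did not pass (11 and 7 adjusted over the list alone; median 0.12, camera adjusted p = 0.294). SLC7A11 and HMOX1 rose. NQO1, a quinone reductase, fell from 181 ± 1.99 to 60.8 ± 9.18 CPM (SD, n = 3 each; edgeR adjusted p = 1.88e-06), and GPX1, a glutathione peroxidase, from 494 ± 29.4 to 202 ± 36.3 CPM. Of 19 AP-1 and immediate early genes, 5 rose, 6 fell and 8 did not pass (6 and 8 adjusted over the list alone; median -0.15, camera adjusted p = 0.649). That median was 0.016 without the genes of chromosome 3. BATF3 fell by 2.48 ± 0.56 and ATF3 rose by 1.49 ± 0.36 (log2, SE). Both lie on chromosome 3, at -2.03 and 1.94 relative to its median. BATF3 had 4, 1 and 18 counts in knockout replicates 1, 2 and 3 and stood at -3.88 without knockout replicate 3. EGR1 was 2.83-fold higher (edgeR adjusted p = 0.0467), with a log2 fold change of 0.95 without wild type replicate 1. NR4A2 (1.14), KLF10 (0.58) and MYC rose too. KLF10 and NR4A2 lost their calls in 5 and 3 of the fits with 1 library left out. Without knockout replicate 3, KLF10 stood at 0.37 (edgeR adjusted p = 0.0950).

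Cholesterol biosynthesis genes were higher on balance: 10 of 28 rose, 2 fell and 16 did not pass (14 and 2 adjusted over the list alone). The median was 0.43 (camera adjusted p = 0.0248; adjusted p = 0.741 with an estimated correlation). The knockout libraries differed among themselves, with list medians against the wild type mean of -0.24 in knockout replicate 1, 0.60 in knockout replicate 2 and 0.66 in knockout replicate 3. The camera adjusted p was 0.145 without knockout replicate 2, 0.171 without knockout replicate 3 and 0.0506 without wild type replicate 1. It was 0.110 with quantile normalization and 0.0691 on log2(RPKM + 0.5), and ran from 3.21e-16 to 0.741 over all alternatives with camera. Fry gave 0.576. STARD4, a sterol carrier, rose by 0.95 ± 0.19 (log2, SE). The lower genes were the fatty acid desaturases FADS2 (-2.72 ± 0.54) and FADS1 (-1.43 ± 0.15), which make polyunsaturated fatty acids and not cholesterol. FADS2 ran from -3.41 to -0.63 over the alternatives. In glycolysis and hypoxia, 5 of 27 rose, 2 fell and 20 did not pass (5 and 2 adjusted over the list alone; median 0.045, camera adjusted p = 0.294). SLC16A3, a lactate exporter, rose by 1.59 ± 0.18 and LDHA (lactate dehydrogenase) by 0.48 ± 0.082. P4HA2, a collagen prolyl hydroxylase, fell by 1.91 ± 0.14 and PFKL by 0.43 ± 0.12. ENO1 (0.37), P4HA1 (0.30) and PFKP (0.23) rose.

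**Figure D4:**
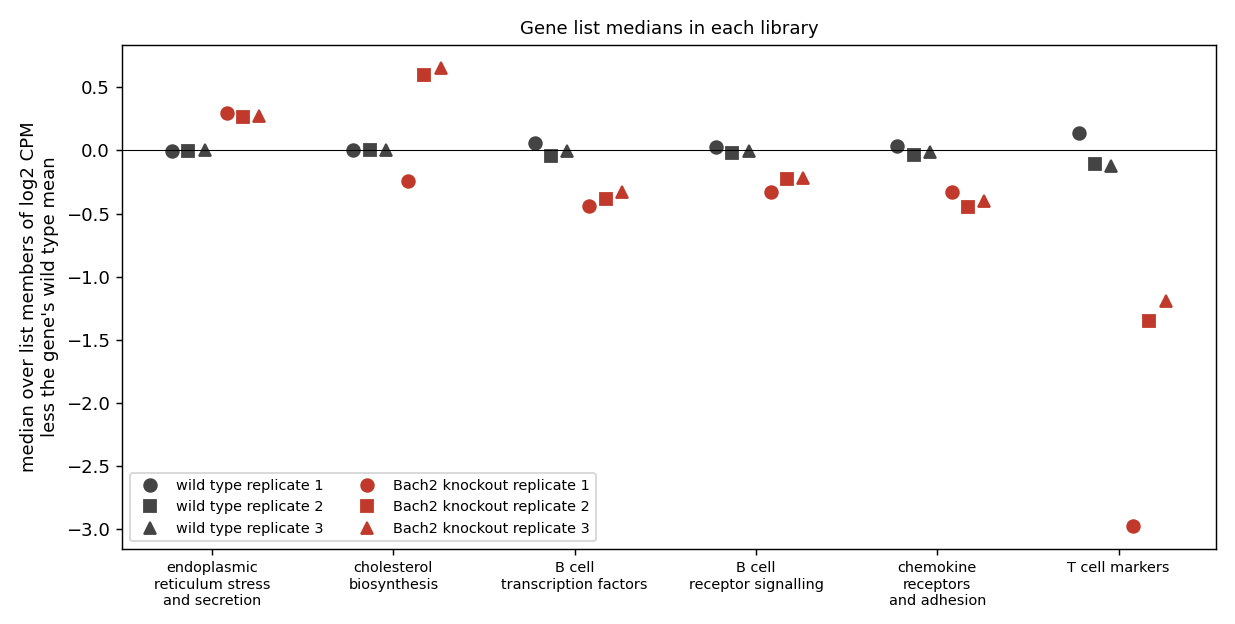
Median over the tested members of 6 lists of log2 CPM less the gene's mean in wild type (vertical axis), for each wild type (grey) and knockout (red) library. The cholesterol list lies at -0.24 in knockout replicate 1 and at 0.60 and 0.66 in knockout replicates 2 and 3, and each of the other 5 lists lies to one side of the wild type libraries in all 3 knockout libraries.

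Lists of cell growth and division did not pass with camera. Of 40 S phase genes, 9 rose, 5 fell and 26 did not pass (10 and 6 adjusted over the list alone; median 0.075, camera adjusted p = 0.164). Of 44 G2 and mitosis genes, 5 rose, 6 fell and 33 did not pass (5 and 6 adjusted over the list alone; median 0.044, camera adjusted p = 0.396). The 5 lower S phase genes and the 6 lower mitosis genes all lie on chromosome 3. Among them, the replication helicase gene MCM3 fell by 0.68 ± 0.073 (log2, SE). It stood at -0.23 relative to the chromosome, where it was still called lower. CASP8AP2 fell by 0.44 ± 0.095 and stood at 0.017, and the checkpoint kinase gene BUB1 fell by 0.61 ± 0.12 and stood at -0.16. NEK2, a kinase of the centrosome, fell by 0.47 ± 0.088 and stood at -0.021, and CENPF, a kinetochore gene, fell by 0.43 ± 0.10 and stood at 0.025. Relative to the chromosome, CASP8AP2, BUB1, NEK2 and CENPF did not pass (edgeR adjusted p = 0.915, 0.347, 0.884 and 0.882). DTL (-0.38) and RRM2 (-0.32) were also among the lower S phase genes. USP1, a deubiquitinase of DNA repair, rose by 0.47 ± 0.071. The higher mitosis genes were HMGB2 (0.41), CDCA3 (0.36), NUF2 (0.35), TACC3 (0.28) and TPX2 (0.23). Among 25 cell cycle inhibitors and p53 targets, 2 rose, 1 fell and 22 did not pass (2 and 0 adjusted over the list alone; median 0.024, camera adjusted p = 0.597). GADD45B was 2.15-fold higher, BTG1 rose by 0.40 ± 0.093 and BTG2 fell by 0.44 ± 0.14.

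Of 54 ribosome biogenesis genes, 13 rose, 8 fell and 33 did not pass, with the same counts adjusted over the list alone (median 0.066, camera adjusted p = 0.164). Of the 8 lower genes, 6 lie on chromosome 3. They include the RNA polymerase I subunit genes POLR1B, which fell by 0.66 ± 0.064 and stood at -0.20 relative to the chromosome, and POLR1C (0.65 ± 0.092 lower, and -0.20). URB2 fell by 0.59 ± 0.075 and stood at -0.13. Relative to the chromosome, POLR1B was still called lower, while POLR1C and URB2 did not pass (edgeR adjusted p = 0.138 and 0.217). Of 64 cytosolic ribosomal protein genes, 9 rose, 3 fell and 52 did not pass (8 and 3 adjusted over the list alone; median 0.072, camera adjusted p = 0.156). The ribosomal list passed camera without wild type replicate 2 (median 0.13, adjusted p = 0.0195) and without knockout replicate 1 (0.095, adjusted p = 0.00398), and its median was 0.022 without knockout replicate 2. Over all alternatives its adjusted p ran from 0.00398 to 0.819. The lower genes, RPS12 (-0.59 ± 0.071), RPS27A (-0.45 ± 0.090) and RPS7 (-0.44 ± 0.066), lie on chromosome 3. Relative to it they stood at -0.14, 0.0053 and 0.012. RPL22L1, on another chromosome, rose by 0.55 ± 0.090. Of 46 oxidative phosphorylation genes, 3 rose, 4 fell and 39 did not pass, with the same counts adjusted over the list alone (median 0.022, camera adjusted p = 0.485). The ATP synthase gene ATP5L fell by 0.69 ± 0.18 and the complex I gene NDUFAB1 rose by 0.46 ± 0.14. COX7A2, of complex IV and on chromosome 3, fell by 0.56 ± 0.088 and stood at -0.11 relative to it. NDUFS6 (0.32) and NDUFA10 (0.28) rose, and NDUFB1 (-0.32) and NDUFB10 (-0.25) fell.

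Among 27 apoptosis regulators, 3 rose, 7 fell and 17 did not pass (3 and 8 adjusted over the list alone; median -0.12, camera adjusted p = 0.294). That median was -0.037 without wild type replicate 1 and -0.019 with quantile normalization. Fry gave an adjusted p of 0.00424, and camera 0.104 to 0.499 over the alternatives. BOK, a member of the BCL2 family, fell from 258 ± 32.5 to 105 ± 16.5 CPM and TNFSF10, the death ligand TRAIL, from 77.3 ± 2.83 to 35.7 ± 5.16 CPM (SD, n = 3 each). BCL2, an inhibitor of apoptosis, rose by 1.26 ± 0.42 from 0.635 CPM in wild type (edgeR adjusted p = 0.0417). BCL2L14 (0.87) and DIABLO (0.28) rose too. Of 14 interferon response genes, 2 rose, 4 fell and 8 did not pass (2 and 5 adjusted over the list alone; median -0.36, camera adjusted p = 0.404). That median was 0.015 with quantile normalization and -0.17 on log2(RPKM + 0.5). Fry gave 0.00424, and camera 0.282 to 0.768 over the alternatives. SOCS1, a suppressor of cytokine signalling, fell by 1.07 ± 0.13 and XAF1 by 1.53 ± 0.50. IRF7, a transcription factor of the interferon response, rose by 1.03 ± 0.20. ADAR (-0.39) and TLR7 (-0.33) fell.

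Markers of other cell types were included as a check on the makeup of the cultures. All 5 tested T cell markers were lower in the knockout, with the same count adjusted over the list alone. Their median was -1.64 (camera adjusted p = 0.000679; adjusted p = 0.317 with an estimated correlation). Against the wild type mean, the list's median was -2.97 in knockout replicate 1, which stood apart on the second component, and -1.35 and -1.19 in knockout replicates 2 and 3. CD3E fell from 17.3 ± 4.04 to 0.820 ± 0.379 CPM and CD3D from 135 ± 14.0 to 96.0 ± 10.8 CPM (SD, n = 3 each). On the log2 scale, CD3E was at -4.33 ± 0.28, a row named CD8A at -4.29 ± 0.37, CD5 at -1.64 ± 0.32, CD247 at -1.07 ± 0.21 and CD3D at -0.49 ± 0.10 (SE). A second row named CD8A was too low to be tested. It had 0.127 ± 0.0860 CPM in wild type and 0.0782 ± 0.0238 CPM in the knockout (SD, n = 3 each). Of 5 macrophage and granulocyte markers, 2 fell, 0 rose and 3 did not pass (2 and 1 adjusted over the list alone; median -0.25, camera adjusted p = 0.191). The median was -0.11 and -0.028 without wild type replicates 1 and 2, -0.61 and -0.70 without knockout replicates 2 and 3, and -0.024 with quantile normalization. Fry gave an adjusted p of 0.00444, and camera 0.142 to 0.627 over the alternatives. The lower markers were CYBB (-1.40 ± 0.13) and MPEG1 (-1.10 ± 0.13), which B cells also express. Of 3 erythroid and thrombocyte markers, EPB41 fell (-0.45 ± 0.083) and 2 did not pass. Of 2 fibroblast markers, the row named for FBN1 was 2.01-fold lower (edgeR adjusted p = 0.0258) and 1 did not pass. In both of these lists the counts adjusted over the list alone were the same, and the lists were too small for camera.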

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

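Leaving out chromosome 3, and taking its genes relative to its median, were chosen after the data were seen. Of the 90 named genes tested, 90 kept direction and side of the threshold with DESeq2 size factors, with library totals only and with any count as the filter. With DESeq2, 88 of 90 did and 2 lost the call, and with limma on each RPKM scale 85 did and 5 lost it. Leaving out 1 library, with fewer samples in the fit, cost between 1 and 11 of these calls. Of the 43 further genes that help complete counts of 5 or fewer, leaving out 1 library cost between 0 and 24 calls, limma 8 on each scale and DESeq2 3. The number of higher genes ranged from 639 to 1483 with 1 library left out. At least 2-fold changes numbered 65 higher and 287 lower among genes with a mean of at least 1 RPKM, where fewer genes were tested. On log2(RPKM + 0.5) and log2(RPKM + 1), where a pseudocount shrinks low genes, 62 and 43 were higher and 273 and 196 lower.

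UNG ranged from -0.096 to 0.025 with 1 library left out, turning direction without knockout replicate 1. IRF4 ranged from -0.21 to -0.063, passing without knockout replicate 1; the cause was not tested. Relative to the median of chromosome 3, CASP8AP2 (0.017), CENPF (0.025), RPS27A (0.0053), SDC1 (0.15), PDIA6 (0.15), DTL (0.076), RRM2 (0.13) and RPS7 (0.012) turned positive, by construction. Without the genes of chromosome 3, 917 genes were higher and 1219 lower. Then 4 lists were called higher, with S phase (adjusted p = 0.0131) and ribosome biogenesis (0.0177) added, MHC class II was called lower (0.0348), and the median of base excision and mismatch repair was 0.064 with its camera direction turned. With an estimated correlation in that fit, the adjusted p was 0.411 for S phase, 0.425 for ribosome biogenesis, 0.366 for MHC class II and 0.0537 for endoplasmic reticulum stress.

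With an estimated correlation, camera called 0 lists higher and 0 lower (unadjusted p = 0.00286 for endoplasmic reticulum stress and 0.0437 for B cell receptor signalling). It called 0 chromosomes higher and 1 lower, with 1 higher at an unadjusted p under 0.05. Fry, which does not compare a list with other genes, called 9 lists lower and 2 higher, endoplasmic reticulum stress (3.57e-05) and the plasma cell programme (0.00148). Quantile normalization and log2(RPKM + 0.5) each left 1 list higher, and leaving out 1 library 1 to 3. Chromosomes called ranged from 0 to 4 higher and from 1 to 3 lower with 1 library left out, with the lowest numbers without knockout replicate 1. The camera direction of lists that did not pass turned for cell cycle inhibitors with the RPKM filter (median 0.027). It turned for AP-1 genes without knockout replicate 1, with medians of -0.25 to -0.10 over the 6 fits; the causes were not tested.

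Deviations from the genotype mean correlated at 0.0036, 0.093 and -0.021 between the same-numbered libraries of replicates 1, 2 and 3. Against libraries with another number these wild type replicates ran from -0.035 to 0.025, -0.058 to -0.0045 and -0.049 to 0.049. Only replicate 2 lay outside its range. With 3 libraries per genotype, this cannot tell whether the numbers pair the samples. With the replicate block, 1009 genes were higher and 1567 lower, and EGR1 (adjusted p = 0.0628) and BCL2 (0.0554) lost their calls, as both did with DESeq2 (0.0648 and 0.0560). Of the 43 further genes, 6 lost theirs with the block. Wild type replicate 3 had the fewest counts, 8999010. PRDM1 had at most 10 counts in any library, and the effect of depth on it was not tested.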

Other observations

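The tests on chromosome copies, regions, T cells and cholesterol genes were chosen after the result was seen; the split of the samples and the matching on length and expression were chosen before.

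Beyond the lists, and named here after their values were seen, the following genes had small p-values. LCP1, the actin-bundling protein L-plastin of leukocytes, fell from 172 ± 9.86 to 21.3 ± 1.28 CPM (SD, n = 3 each; log2 fold change -3.02, edgeR adjusted p = 9.13e-09). COTL1, another actin-binding protein, had a log2 fold change of -1.94. The growth factor gene MDK fell from 451 ± 8.93 to 70.7 ± 9.12 CPM and ANXA2 from 76.0 ± 6.75 to 22.7 ± 0.736 CPM. DNMT3A, a de novo DNA methyltransferase, fell from 30.6 ± 3.04 to 3.99 ± 1.12 CPM. It lies on chromosome 3, at -2.46 relative to its median. Among higher genes, NREP rose from 37.2 ± 2.61 to 106 ± 7.65 CPM, ENTPD1, the ectonucleotidase CD39, from 12.6 ± 0.740 to 41.8 ± 3.09 CPM and STMN2 from 173 ± 3.17 to 359 ± 20.3 CPM. No enrichment was tested for these genes.

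Silence was one-sided. Of genes with at least 20 counts in total over the libraries of the other genotype, 26 had 0 counts in all 3 knockout libraries, among them UNC79, TRANK1 and EPHB2, and 1, HPGDS, had 0 counts in all 3 wild type libraries. The knockout libraries held 50030601 counts in all and the wild type libraries 43524981, so that the side with more silent genes was the deeper one.

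Of the 10 ways to split the 6 libraries into 3 and 3, only the real one called any gene with edgeR's quasi-likelihood test. It called 2810 genes, against 0 in the highest of the other 9, where up to 232 genes had an unadjusted p under 0.05. Each of these 9 mixes the genotypes, so that the genotype difference widens the spread within its groups. Their 0 calls are thus no measure of what chance gives. Besides, 10 splits are too few for a share under 0.05.

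Genes along the whole of chromosome 3 were lower in the knockout libraries. The tables argue against a few regions of regulated neighbours, since 100% of the bins along the chromosome had a median below 0, and against gene length or expression level, since the genes lay 0.49 below genes of other chromosomes matched on both (difference -0.49, bootstrap interval -0.51 to -0.46). That interval is of a median over 688 genes and does not measure the spread between clones. In knockout replicates 1, 2 and 3, the chromosome's median against the wild type mean was -0.42, -0.45 and -0.48. The hypothesis that the knockout cells carry fewer copies of this chromosome per genome than the wild type cells remains open. No test here decides it. The highest bin median was -0.30, but any decrease along the whole chromosome, with 93.6% of its genes below 0, would give that. The chromosome's median was -0.45, a difference of -0.48 to the median of genes placed on other chromosomes. A ratio of 2 to 3 would give -0.58. Other ratios were not compared, so that these values do not speak against fewer copies. Under that hypothesis, part of the lower calls, including those of REV3L, PARP1 and BUB1, may follow from the clone and not from Bach2. These data cannot separate such causes, and no copy number was measured.

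T cell marker genes were lower in the knockout, which T cells among the wild type cells could have produced. Against this, the other 21 T cell list genes, of which 17 lay under 1 CPM, had a median of 0.0243 CPM in wild type, against 17.3 CPM for CD3E, and 8 genes of the list, among them CD28, IL7R and CD4, had no count in any library; CD3D stood at 135 CPM in wild type and 96.0 CPM in the knockout. A change in the B cells themselves remains as a hypothesis, for which no further test was made.

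Cholesterol biosynthesis genes were higher in knockout replicates 2 and 3, where 26 of 28 lay above the wild type mean, and not in knockout replicate 1, where 5 did. The median in knockout replicate 1 was -0.24. The tables argue against fewer reads in that library, since wild type replicate 3, the shallowest library, differed from wild type replicate 1, the deepest, by -0.00076 in the list's median. A difference between cultures, such as density or medium, may underlie it and was not tested, since the labels give no such variable. An effect of Bach2 on these genes stays open as well and was not tested apart from it.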
